A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

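Polyadenylated RNA of a bre1 strain and of wild-type Saccharomyces cerevisiae was labelled with Cy3 or Cy5 and hybridised together on 4 2-colour arrays. Per the labels, bre1 RNA carried Cy3 on arrays 1 and 3 and Cy5 on arrays 2 and 4, and the arrays form a dye-swapped set of 4. The labels refer to another publication for growth, extraction and labelling, which was not used here. All 4 arrays make 1 group, each array being a ratio between bre1 and wild type.

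The values are log ratios of the 2 channels as the authors deposited them, 1 per reading frame and array, and were read as log2 ratios. Their normalization, background correction, spot filter, centring, direction and log base are not given in the sources used here. Base 2 was chosen because the values lie between -4.80 and 2.82, which as log10 or natural log ratios would span far wider folds. Whether the arrays run the same way was decided by a rule fixed beforehand: had arrays of opposite dye correlated below 0, those with bre1 in Cy3 would have been turned; they correlated above 0 and no sign was changed. This rule cannot tell bre1 over wild type from wild type over bre1. Nor can it exclude values that were never turned, with a dye bias larger than the bre1 effect. The first was taken, from the order of the names in the sample descriptions and from the low ratio of BRE1 on the 2 arrays that measured it, and is likely but not settled. Scanner intensities were not analysed here, so no filter on dim spots was possible, and the number of arrays limits the precision. If the deposited ratios were normalized within each array to a median near 0, a change of all transcripts together would not be seen, and each ratio is relative to the other genes of its array.

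The value table held 5500 reading frames, 474 of them with no value on any array and 1186 with values on 1 to 3 arrays. The 3840 with values on all 4 arrays were tested. Systematic names were matched to a gene table of assembly R64, which named 5470 of the 5500 frames and left 30 unmatched, 19 of them among the tested genes; those keep their systematic names. The values name no genome build, so no coordinates are printed, and the gene table served for names, gene lengths (introns included), neighbours and gene order. Near-identical genes (CUP1, Y′ reading frames, PAU, COS, HXT, TIR, PHO11 and PHO12, FEX1 and FEX2, ribosomal protein pairs) may share probe signal, and their values are uncertain as separate genes.

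Genes were tested in R 4.3.3 with limma 3.58.1: lmFit with an intercept alone on the 4 ratios, eBayes moderation, a two-sided test of the mean log2 ratio against 0 and Benjamini-Hochberg adjustment over 3840 genes, with a threshold of 0.05. The design holds both dye orientations equally, so that a dye effect of a gene cancels in the mean and stays in the spread, if the values run the same way. Errors are SDs over arrays. Fixed gene lists were tested with limma's camera with a preset correlation between genes of 0.01, adjusted over the lists. They were tested again with the correlation estimated from 3 residual degrees of freedom per gene, and none of the 15 lists that passed kept its call. That run also lowers the degrees of freedom of the test itself to 3, so it cannot tell whether correlation between genes removed a call. The a-specific, pheromone and general stress lists had estimated correlations of -0.23, -0.09 and -0.01, below the preset, and still lost theirs. Of 33 lists, 2 had fewer than 3 measured genes and were not tested. Lists, tests, alternatives and the rule for named genes were written before the data were examined, except where the text says otherwise.

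The genes named are BRE1, the 12 with the largest mean rise and the 12 with the largest mean fall among genes past the threshold with 1 sign on all 4 arrays, up to 4 members past the threshold per list (or the 2 with the smallest p where none passed), 2 neighbours of BRE1 on each side, and members of lists of at most 6 genes. The values of 2 genes that this rule names are not reported here. Subtelomeric genes had been planned as those within set distances of a chromosome end. Chromosome lengths were not used here, so the outermost 10 protein-coding genes at each of 32 ends were taken in their place, with the outermost 5 and 15 as alternatives. A list of transposon genes was not run. BRE1 had values on 2 arrays and was therefore described without a test.

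The tests were tried on simulated data of 3840 genes with the observed spread, of which 67, 67 and 66 were changed by 0.5, 1 and 2 on the log2 scale. With independent arrays these changes were recovered in 20.9%, 97.0% and 100% of genes, with 4.61% false genes among those called. With dye and pair effects scaled from the contrasts seen here the shares were 19.4%, 86.6% and 100%, with 2.84% false. In that run the error of the mean was set equal to the contrast between arrays 1 and 2 and arrays 3 and 4. Genes were drawn independently in both runs. Error shared by all 4 arrays cannot be seen in these data, so the false shares do not measure it for the genes called below. Alternatives were median centring, scaling between arrays, a dye term, genes with values on at least 3 arrays, a robust variance prior, array weights, each array left out, the arrays averaged as dye-swap pairs, a stricter threshold of 0.01, a minimum change of 1.5-fold, the set test fry, and, added after the data were seen, removal of a trend on gene length (natural spline with 4 degrees of freedom per array), a dye term with each array left out, the ribosomal protein list without RPP1, the estimated correlation for the subtelomeric list without repeated families, and ribosomal protein genes set against the 20 other genes nearest in length on each array. Figures were drawn with Python 3.11 and matplotlib 3.10.9.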

Results

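Polyadenylated RNA of a budding yeast (Saccharomyces cerevisiae) strain named bre1 was compared with that of wild type on 4 2-colour microarrays. BRE1 encodes the ubiquitin ligase that, with the conjugating enzyme Rad6, attaches ubiquitin to histone H2B, a mark needed for methylation of histone H3 by Set1 and Dot1. The labels name the strain only as bre1, in the lower case that yeast genetics uses for a mutant, and do not give the kind of mutation. On arrays 1 and 3 the bre1 RNA carried Cy3 and the wild-type RNA Cy5, and on arrays 2 and 4 the dyes were exchanged. Each array gave 1 log ratio per reading frame, for 4354, 4561, 4759 and 4607 of the 5500 listed frames on arrays 1 to 4. The median log2 ratio was -0.02, 0.07, -0.05 and 0.07 on these arrays, and the SD over genes was 0.67, 0.57, 0.49 and 0.49. The labels do not say whether the 4 arrays came from separate cultures, so p-values measure only the spread between arrays, which may be technical.

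The first comparison asked which way the ratios run, since the labels give the dyes and not the direction. Over the 3840 genes with a value on every array, arrays of opposite dye orientation correlated positively, with Pearson r of 0.65 for arrays 1 and 2, 0.31 for arrays 2 and 3, 0.24 for arrays 1 and 4 and 0.20 for arrays 3 and 4 (correlations across genes, which are not independent replicates). Arrays of the same dye orientation gave r of 0.75 for arrays 1 and 3 and 0.54 for arrays 2 and 4. The values of the 4 arrays were therefore taken as running the same way. Values never turned, with a dye bias larger than the bre1 effect, could also correlate positively. BRE1 has values on arrays 1 and 3 only, where bre1 RNA carried Cy3, at log2 ratios of -1.65 and -3.17. If bre1 lacks the transcript, unturned Cy5 over Cy3 values would be high there, so these values argue against that form. Unturned Cy3 over Cy5 values would be low there too, and BRE1 cannot check that form without arrays 2 and 4. The correlations do not tell which way, since they would be the same if every value were wild type over bre1. The values were read as bre1 over wild type because the samples name bre1 first and because BRE1 was low on that reading. This direction is likely and not settled, and on the opposite reading each rise would be a fall. The log base is not given either and was read as 2.

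Read this way, BRE1 itself (YDL074C) was lower in bre1 on both arrays that measured it, 3.14-fold on array 1 and 8.98-fold on array 3. Its mean log2 ratio was -2.41 ± 1.07 (SD, n = 2 arrays). Neither array with bre1 RNA in Cy5 gave a value for BRE1, so the gene was outside the test, which needed all 4 arrays, and its direction rests on a single dye orientation. Of the 2 genes on each side of BRE1, the ribosomal protein gene RPL31A rose (log2 ratio 0.99 ± 0.59, SD, n = 4, adjusted p = 0.031). RXT3, AHK1 and YET3 did not pass the threshold, with mean log2 ratios of 0.43, -0.07 and 0.10.

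The main comparison asked which transcripts differed between bre1 and wild type. The 12 genes with the largest rise were led by FUN30 (YAL019W), which encodes a chromatin remodeller of the Snf2 family and was 4.21-fold higher in bre1 (log2 ratio 2.07 ± 0.33, SD, n = 4, adjusted p = 0.0032). CUP1-1 and CUP1-2, which encode the copper-binding metallothionein, were 3.98-fold and 3.93-fold higher (log2 ratios 1.99 ± 0.69 and 1.97 ± 0.74). These are near-identical copies whose signals may not be separable. CDC15, a kinase of the mitotic exit network, was 3.72-fold higher, ARG1, the argininosuccinate synthetase of arginine synthesis, 3.58-fold, and OGG1, a DNA glycosylase that removes oxidised guanine, 3.39-fold. The remaining genes of this group were RIB4 of riboflavin synthesis (3.06-fold), YNR064C (2.91-fold), the Mediator subunit gene SOH1 (2.76-fold), the kinase gene TOR2 (2.68-fold), RPS10A of the small ribosomal subunit (2.55-fold) and QCR8 of respiratory complex III (2.52-fold). Adjusted p-values of the 12 lay between 0.0032 and 0.0200.

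The 12 genes with the largest fall were led by PHO84 (YML123C), the high-affinity phosphate transporter, which was 4.34-fold lower in bre1 (log2 ratio -2.12 ± 0.79, SD, n = 4, adjusted p = 0.0071). The cell wall mannoprotein genes TIR4, DAN1 and TIR2 were 4.19-fold, 2.90-fold and 2.50-fold lower. Among genes of membrane proteins, PNS1 was 3.21-fold lower, the polyamine transporter gene TPO1 2.92-fold, the siderophore transporter gene ARN1 2.81-fold, the plasma membrane proton pump gene PMA1 2.77-fold, the glucose transporter gene HXT1 2.75-fold and STE2, the receptor for alpha-factor, 2.46-fold. CTS1, the chitinase that parts daughter from mother cells, was 2.51-fold lower, with a wide spread between arrays (log2 ratio -1.33 ± 1.01). YLL067C, a reading frame of the Y′ repeats at chromosome ends, was 2.56-fold lower. Adjusted p-values of these 12 lay between 0.0071 and 0.0380, and all 24 genes had the same sign on all 4 arrays, as the rule for naming them required.

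**Figure D1:**
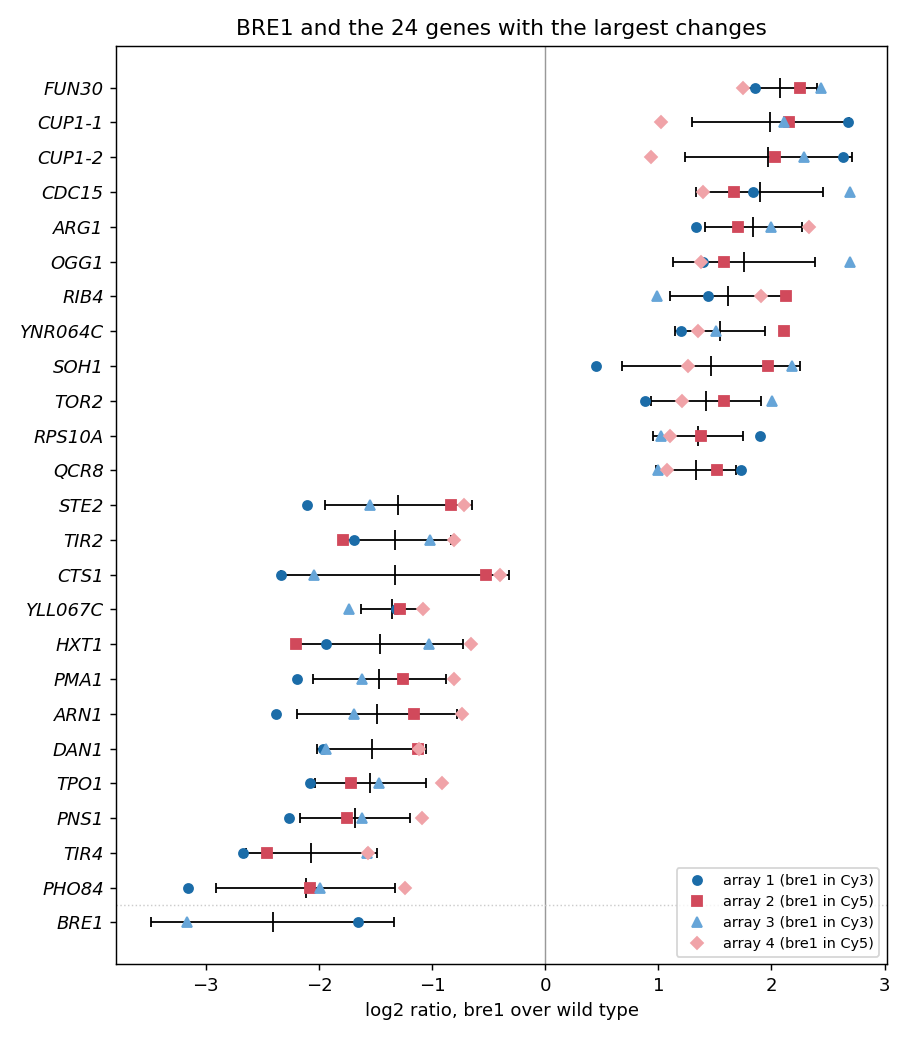
Log2 ratio of bre1 over wild type (x axis) for BRE1 and the 24 genes with the largest changes, 1 point per array, coloured and shaped by array and dye orientation; the vertical tick is the mean and the horizontal bar 1 SD on either side. FUN30 lies between 1.74 and 2.44 on the 4 arrays and PHO84 between -3.16 and -1.24, while BRE1 has values on arrays 1 and 3 only.

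In all, 410 of 3840 genes (10.7%) passed an adjusted p under 0.05 in limma's test of the mean log2 ratio against 0, 226 higher and 184 lower in bre1. Of these, 217 of the higher and 174 of the lower genes changed at least 1.5-fold, and 46 and 54 at least 2-fold. The sign was the same on all 4 arrays for 1371 of all 3840 genes (35.7%). Independent arrays without any effect would give 12.5%, and arrays that share error would give more. Among the 410 genes the sign was the same for 406, which the test itself favours, since it selects means far from 0 for their spread. The 4 exceptions, named after their values were seen, were RPS30B, PBI2, COX17 and YJL188C, each higher on arrays 1 to 3 and between -0.22 and -0.02 on array 4. The count rested on which arrays entered: without array 1 it was 54, without array 3 it was 187 and without array 4 it was 677, and without array 2 no gene passed in limma, although 815 had an unadjusted p under 0.05. A fit with a dye term gave 897 genes, among them all 410.

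The gene lists asked which functions changed together; 31 lists had enough measured genes and 15 of them passed, 3 higher and 12 lower in bre1. Genes of the translation machinery were the largest group that rose. Of 108 measured genes of cytosolic ribosomal proteins, 41 rose and none fell (57 rose adjusted over the list alone), with a median log2 ratio of 0.66. The list took in RPP1, a subunit of RNase P and not a ribosomal protein, by its name (noticed after the data were seen); RPP1 had a log2 ratio of -0.02 ± 0.21, and without it 41 of 107 genes rose, with a median of 0.67. RPS10A was 2.55-fold higher, RPS31 2.43-fold, RPL24A 2.14-fold and RPL43A 2.09-fold. The list passed camera with a preset correlation (adjusted p = 1.7e-16), with adjusted p = 0.447 with an estimated correlation. The list's median was 0.59, 0.89 and 0.98 on arrays 1, 2 and 4, and -0.01 on array 3, where the median of all measured genes was -0.05. Many of these genes come in near-identical pairs whose probes may read both copies.

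Ribosome biogenesis genes, which act in making and assembling ribosomal RNA and subunits, were also higher. Of 56 measured, 6 rose and none fell (11 adjusted over the list alone), and the median log2 ratio was 0.32 (camera adjusted p = 1.1e-05; adjusted p = 0.355 with an estimated correlation). RPA34, a subunit of RNA polymerase I, was 1.99-fold higher, NOP12 1.70-fold, NOP13 1.58-fold and the helicase gene RRP3 1.46-fold. The list's median was above 0 on each array, from 0.21 to 0.38.

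Proteasome genes, which encode the protease that degrades ubiquitinated proteins, were the third group. All 28 measured genes had a mean above 0, 5 rose and none fell (7 adjusted over the list alone), and the median was 0.37 (camera adjusted p = 4.1e-05; adjusted p = 0.468 with an estimated correlation). RPN5 was 1.94-fold higher, RPT2 1.85-fold, RPN8 1.72-fold and PRE9 1.67-fold, and the remaining gene that rose was RPT4. The median on array 3 was -0.04, against 0.25 to 0.85 on the others, and without array 4 the list's median was 0.21 (adjusted p = 0.00265).

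A further measured fact stands beside these 3 lists, since ribosomal protein genes are short. Genes of at most 500 bp (annotated length, introns included) had a median log2 ratio of 0.36, with 61 of 294 higher and 8 lower, and those over 2000 bp had a median of -0.05, with 17 of 866 higher and 38 lower. The bins between had medians of 0.18, 0.03 and -0.05. Without ribosomal protein and ribosome biogenesis genes the shortest bin still had a median of 0.33. Length was examined only after the data were seen.

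Several groups of nutrient uptake and metabolism fell. Of 12 measured genes of the phosphate regulon, all had a mean below 0 and 4 fell (6 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 6.3e-05; adjusted p = 0.386 with an estimated correlation). PHO84 was followed by VTC3 of polyphosphate synthesis, 1.84-fold lower, and by the acid phosphatase genes PHO12 and PHO11, 1.68-fold and 1.63-fold lower, which are near-identical copies. Of 14 measured genes of the iron regulon, 4 fell (10 adjusted over the list alone), with a median of -0.67 (camera adjusted p = 5.7e-05; adjusted p = 0.459 with an estimated correlation). These were the siderophore transporter genes ARN1 and ENB1, 2.81-fold and 2.25-fold lower, the ferric reductase gene FRE2, 2.09-fold lower, and SMF3, a metal transporter gene, 2.02-fold lower. The iron list's median lay between -0.94 and -0.78 on arrays 1 to 3 and at -0.08 on array 4.

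All 14 measured genes of glycolysis and fermentation had a mean below 0, but no single gene passed, over all genes or adjusted over the list alone. Their median was -0.53 (camera adjusted p = 6.1e-04; adjusted p = 0.468 with an estimated correlation). The smallest p-values were those of PFK2 (log2 ratio -0.83 ± 0.64) and PGI1 (-0.68 ± 0.49), with adjusted p of 0.054 and 0.061. The list's median was -1.21, -0.48 and -0.82 on arrays 1 to 3 and 0.29 on array 4; without array 4 it was -0.81, and without array 1 it was -0.34.

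Genes of the general stress response, most of them induced by heat, starvation or oxidants, were lower as a group. Of 20 measured, 4 fell (5 adjusted over the list alone), and the median was -0.33 (camera adjusted p = 0.0012; adjusted p = 0.355 with an estimated correlation). ALD3, an aldehyde dehydrogenase gene, was 1.63-fold lower, PGM2 of glycogen metabolism 1.62-fold, and the chaperone genes HSP26 and SSA4 1.60-fold and 1.49-fold. The list's median was below 0 on each array, from -0.44 to -0.27.

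Genes of meiosis and sporulation, normally silent in growing haploid cells, were lower too. Of 11 measured, 4 fell (6 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 4.3e-04; adjusted p = 0.355 with an estimated correlation). SMK1, a kinase of spore wall formation, was 2.10-fold lower, REC114 of recombination initiation 1.71-fold, SPO13 1.70-fold and the recombinase gene DMC1 1.53-fold. The list's median was below 0 on each array, from -0.65 to -0.25. Of 24 members listed on the array, 11 had values on all 4 arrays. Scanner intensities were not analysed, so it is not known whether these spots lay near background.

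Mating genes had lower medians, with weaker support. Of 4 measured a-specific genes, which are expressed in cells of mating type a, STE2 fell (2 of 4 adjusted over the list alone), and the median was -0.49 (camera adjusted p = 0.033; adjusted p = 0.355 with an estimated correlation). The other 3 did not pass over all genes, with mean log2 ratios of -0.57 for STE6, -0.40 for MFA1 and -0.05 for MFA2. None of 8 measured pheromone response genes passed, over all genes or adjusted over the list alone. Their median was -0.37 (camera adjusted p = 0.029, and adjusted p = 0.355 with an estimated correlation). PRM1 and KAR4 had the smallest p-values, with log2 ratios of -0.52 ± 0.17 and -0.51 ± 0.38. Outside the test, AGA1, SST2 and FUS1 had mean log2 ratios of -1.45, -1.43 and -0.70 over 3 arrays each. PRM2 and PRM3 had -0.47 and -0.20 over 3 arrays each, and FUS2 had 0.31 over 2 arrays. The call for the a-specific list was lost without array 4 (adjusted p = 0.119) and with array weights (0.058), and that for the pheromone list without array 2 (0.095), without array 4 (0.074) and with a robust variance prior (0.057). Of the alpha-specific genes, too few were measured for a list test: AFB1 was 2.38-fold lower (adjusted p = 0.00764) and SAG1 had a log2 ratio of -0.32 ± 0.32. STE3, untested for lack of a value on array 4, ran the other way, at 0.68, 0.12 and 0.62 on arrays 1 to 3. MF(ALPHA)2 was at -0.07 on array 2 and 0.41 on array 3, and MF(ALPHA)1 had no value. The labels do not give the mating type of the strains.

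Genes of daughter cell separation, whose products dissolve the septum after division, fell in part. Of 7 measured, 4 fell, also adjusted over the list alone, with a median of -0.73 (camera adjusted p = 0.0098; adjusted p = 0.459 with an estimated correlation). CTS1 was 2.51-fold lower, DSE2 2.42-fold, SUN4 1.98-fold and EGT2 1.66-fold. The list's median ranged from -1.14 on array 1 to -0.17 on array 4.

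Of 4 measured anaerobic cell wall genes, which encode mannoproteins made when oxygen is scarce, TIR4, DAN1 and TIR2 fell, over all genes and adjusted over the list alone, and TIR3 had a log2 ratio of -0.38 ± 0.48. The median was -1.43 (camera adjusted p = 1.3e-04; adjusted p = 0.355 with an estimated correlation), and it lay between -1.83 and -0.96 on the 4 arrays. All 15 measured seripauperin genes (PAU), a family of cell wall mannoprotein genes near chromosome ends, had means below 0. Of these, 2 fell over all genes, PAU17 and PAU20 (both 1.46-fold lower), and 14 fell adjusted over the list alone, with a median of -0.49 (camera adjusted p = 1.1e-06; adjusted p = 0.355 with an estimated correlation). With the trend on gene length removed the seripauperin median was -0.81. All 8 measured COS genes, another subtelomeric family of membrane proteins, also had means below 0; COS7 and COS3 fell, 2.03-fold and 1.71-fold, and all 8 passed adjusted over the list alone, with a median of -0.77 (camera adjusted p = 6.4e-05; adjusted p = 0.459 with an estimated correlation). Members of these families share sequence, so that a probe may read several of them and their number overstates the separate measurements.

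**Figure D2:**
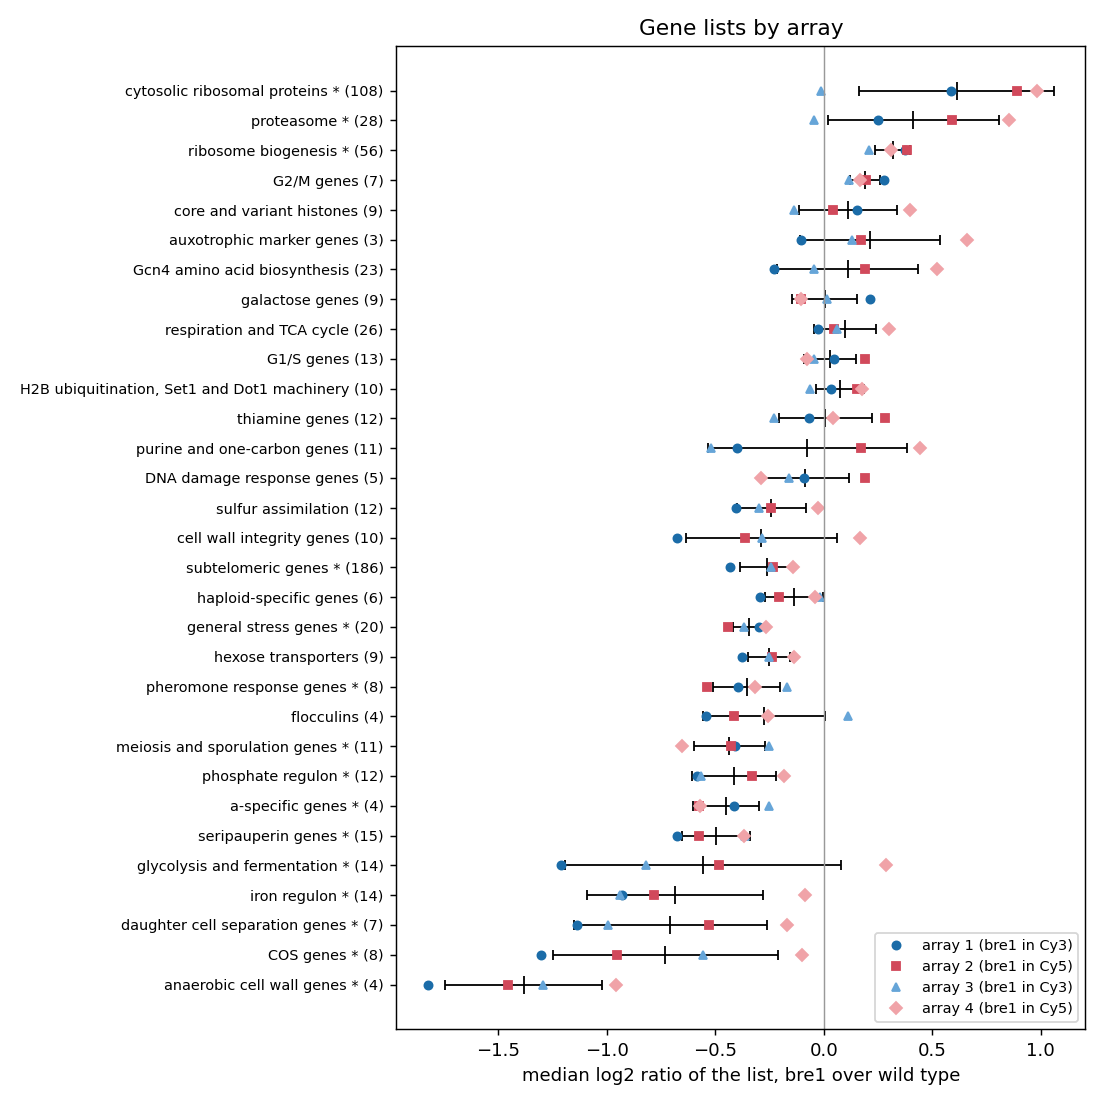
Median log2 ratio, bre1 over wild type (x axis), of each fixed gene list on each of the 4 arrays; the number of measured genes is in brackets, the vertical tick is the mean of the 4 medians, the bar is 1 SD on either side, and an asterisk marks lists past an adjusted p of 0.05 in camera with the preset correlation. The ribosomal protein and proteasome medians lie above 0 on arrays 1, 2 and 4 and near 0 on array 3, and the anaerobic cell wall genes have the lowest medians, from -1.83 to -0.96.

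The remaining 16 lists did not pass. Medians given for them without several arrays leave out 1 array at a time. Among the genes of H2B ubiquitination and of the Set1 and Dot1 complexes, the group closest to Bre1, 1 of 10 measured rose (2 adjusted over the list alone) with a median of 0.06 (adjusted p = 0.449). The gene that rose was RAD6, the partner of BRE1 in ubiquitination, at 1.61-fold (log2 ratio 0.69 ± 0.16, adjusted p = 0.028). Of 9 histone genes, HHF2, which encodes histone H4, was 1.68-fold higher, also adjusted over the list alone, with a median of 0.17 (adjusted p = 0.235). The histone median was 0.26, 0.08 and 0.11 without arrays 2, 3 and 4, and -0.04 with the length trend removed. The median of the H2B list was 0.14 without array 3 and 0.02 with the length trend removed. The silencing list of SIR genes and silent mating loci had too few genes measured for a test. Its member on all 4 arrays, HMLALPHA2, had a log2 ratio of 0.05 ± 0.67 (adjusted p = 0.911). That mean joins 0.40 and 0.81 on arrays 1 and 3 with -0.48 and -0.54 on arrays 2 and 4. HMRA2, outside the test, was at 0.86, 0.26 and 0.76 on arrays 1 to 3, with no value on array 4. SIR1 and SIR2 had means of 0.13 and 0.02 over 3 arrays each.

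Of 9 hexose transporter genes, HXT1, HXT2 and HXT5 fell, 2.75-fold, 2.23-fold and 1.95-fold (4 adjusted over the list alone), but the list did not pass (median -0.33, adjusted p = 0.120). It passed with arrays 1 and 2 and arrays 3 and 4 averaged as pairs (adjusted p = 0.0096), but not with all 4 arrays and the correlation estimated (adjusted p = 0.468 with an estimated correlation), while its median was -0.0074 with values on at least 3 arrays and -0.22 with the length trend removed. Of 26 genes of respiration and the TCA cycle, 4 rose and 1 fell, also adjusted over the list alone. QCR8 and QCR7 of complex III were 2.52-fold and 1.89-fold higher, ATP7 1.72-fold and COX5A 1.63-fold, while the aconitase gene ACO1 had a log2 ratio of -0.88 ± 0.56 (list median 0.10, adjusted p = 0.262; medians of 0.17 without array 3, 0.0057 without array 4 and 0.03 with the length trend removed). Of 23 Gcn4-regulated genes of amino acid synthesis, 3 rose, also adjusted over the list alone, among them ARG1 at 3.58-fold and HIS4 at 1.81-fold (list median 0.12, adjusted p = 0.226; adjusted p = 0.776 with an estimated correlation). That list passed without array 1 (median 0.21, adjusted p = 0.032) and with values on at least 3 arrays (0.21, adjusted p = 0.028), and did not pass without arrays 2, 3 or 4, with medians of 0.02, 0.25 and 0.02. Of 10 cell wall integrity genes, CWP1 and KTR2 fell, 2.15-fold and 1.98-fold, also adjusted over the list alone; the list missed the threshold (median -0.22, adjusted p = 0.078; adjusted p = 0.468 with an estimated correlation). It passed without array 4 (median -0.37, adjusted p = 0.040) and with a dye term (0.048), and without array 1 its median was -0.06 (adjusted p = 0.073).

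Among cell cycle lists, 2 of 13 G1/S genes fell, among them RNR1 of nucleotide synthesis at 1.82-fold (1 higher and 2 lower adjusted over the list alone). That list's median was 0.08 while its mean was -0.04, the sign that camera followed (adjusted p = 0.878), and without arrays 1, 2 and 3 the median was 0.02, -0.05 and 0.18. None of 7 G2/M genes passed, also adjusted over the list alone, with a median of 0.18 (adjusted p = 0.185; 0.028 in fry's directional test, which does not compare a list with other genes); BUD4 and IQG1 had log2 ratios of 0.54 ± 0.29 and 0.36 ± 0.18. None of 5 DNA damage response genes passed, also adjusted over the list alone, with a median of -0.07 (adjusted p = 0.782) that was -0.11, -0.17 and -0.0056 without arrays 1, 2 and 3 and 0.04 with the length trend removed, DUN1 and RNR3 having log2 ratios of 0.37 ± 0.30 and -0.35 ± 0.25. None of 6 haploid-specific genes passed, also adjusted over the list alone, with a median of -0.24 (adjusted p = 0.253) and of -0.12 without array 3; FAR1 and FUS3 had log2 ratios of -0.38 ± 0.33 and -0.25 ± 0.27.

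In the metabolic lists that did not pass, GAL1 of galactose use rose 1.47-fold (1 of 9 genes, also adjusted over the list alone; median 0.12, adjusted p = 0.982; medians of 0.05, -0.0093 and 0.04 without arrays 1, 2 and 3). THI5 of thiamine synthesis rose 1.46-fold (1 of 12 genes, 2 adjusted over the list alone; median 0.05, adjusted p = 0.878; medians of -0.03, 0.03 and 0.02 without arrays 2, 3 and 4). GCV2, a subunit of glycine decarboxylase, fell 1.73-fold (1 of 11 purine and one-carbon genes, also adjusted over the list alone; median -0.03, adjusted p = 0.609; medians of 0.01, -0.09, 0.06 and -0.19 without arrays 1 to 4 in turn). None of 12 sulfur assimilation genes passed, also adjusted over the list alone, with a median of -0.16 (adjusted p = 0.177) and of -0.26 without array 4 and -0.09 with the length trend removed; SUL1 and MET2 had log2 ratios of -0.49 ± 0.05 and -0.51 ± 0.38. None of 4 flocculin genes passed, also adjusted over the list alone, with a median of -0.38 (adjusted p = 0.123; adjusted p = 0.520 with an estimated correlation); FLO5 and FLO9 had log2 ratios of -0.44 ± 0.28 and -0.34 ± 0.27. Without array 3 the flocculin list passed (median -0.47, adjusted p = 0.027), and without array 2 its median was -0.23 (adjusted p = 0.238). Among 3 auxotrophic marker genes, which differ between laboratory strains by construction, HIS3 rose 2.45-fold (1 of 3, also adjusted over the list alone; median 0.13, adjusted p = 0.244), and TRP1 and ADE2 had log2 ratios of 0.13 and -0.11. The marker median was 0.21, 0.23 and -0.05 without arrays 1, 2 and 4, and the list passed with values on at least 3 arrays (adjusted p = 0.0051), but not with all 4 arrays and the correlation estimated (adjusted p = 0.468 with an estimated correlation).

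The next comparison asked about genes close to chromosome ends, where histone marks that depend on Bre1 bear on silencing. Of 186 measured genes among the outermost 10 protein-coding genes at each of the 32 chromosome ends, 39 fell and 4 rose (59 and 9 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 1.5e-07; adjusted p = 0.355 with an estimated correlation and 0.0535 in fry's directional test). Among those that fell, YLL067C, YRF1-2, YIL177C and YRF1-5, all reading frames of the Y′ repeats, had the smallest p-values and were 2.56-fold, 2.24-fold, 2.15-fold and 2.14-fold lower. The 4 that rose, named after their values were seen, were SFT2 (log2 ratio 0.88 ± 0.31), OPT2 (0.74 ± 0.33), KGD4 (0.63 ± 0.28) and THI5 (0.55 ± 0.11). Y′ reading frames are near-identical, so that these are not separate measurements.

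By position, 29 of 90 measured genes in places 1 to 5 from an end fell and none rose, with a median of -0.45, which was below 0 on each array (-0.68, -0.52, -0.35 and -0.31). Many of the 29 were Y′ reading frames, among them YRF1-2, YRF1-3, YRF1-5, YLL067C and YIL177C. These are near-identical, so that the count overstates the separate measurements. In places 6 to 10, 10 of 96 fell and 4 rose, with a median of -0.15. In places 11 to 15, 6 of 92 fell and 4 rose, with a median of -0.10, and in places 16 to 20, 5 of 105 fell and 8 rose, with a median of -0.02. Beyond place 20, 129 of 3428 genes fell and 208 rose, with a median of 0.04. Without the repeated families the list had a median of -0.19 (camera adjusted p = 2.4e-05, and adjusted p = 0.386 with an estimated correlation). These families were taken out by gene name (PAU, COS, YRF1, DAN, TIR, FLO and HXT). Y′ reading frames with systematic names alone, such as YLL067C and YIL177C, stayed in. That median therefore does not show the list free of repeats.

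**Figure D3:**
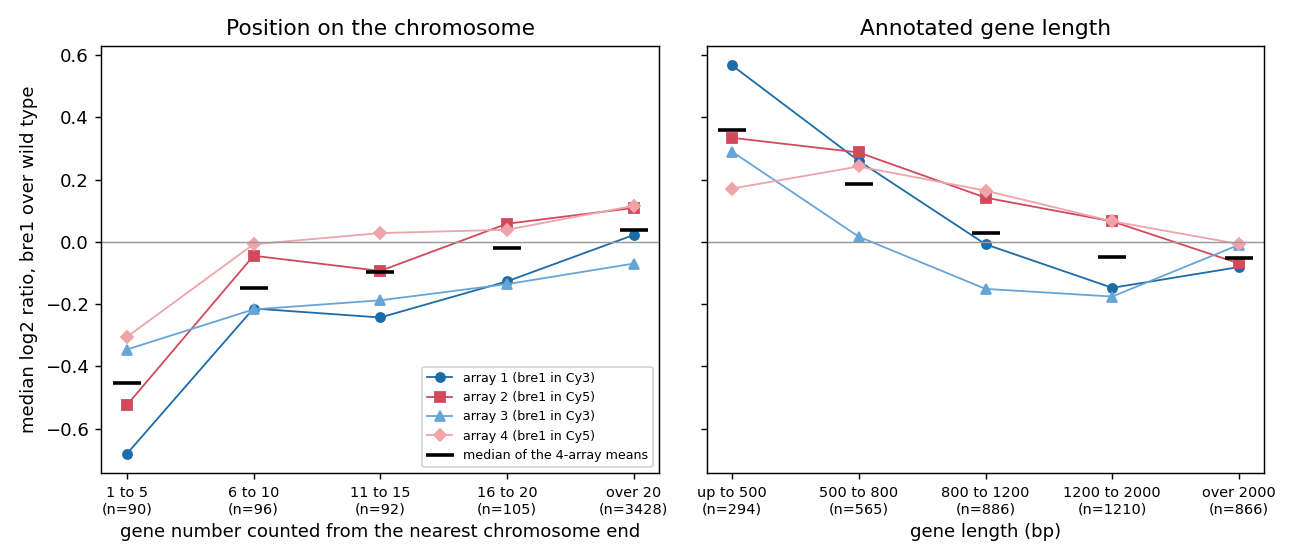
Median log2 ratio, bre1 over wild type (y axis), by place counted from the nearest chromosome end (left) and by annotated gene length in bp (right); lines are the 4 arrays, black bars the median of the 4-array means, and n the number of measured genes. Genes in places 1 to 5 lie at -0.45 and genes of at most 500 bp at 0.36, and both hold the same sign on all 4 arrays.

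The last comparisons asked whether whole chromosomes or the dyes shifted the ratios. Taken relative to the median of all genes on each array, the median of chromosome IX lay farthest from 0, at -0.09 ± 0.06 (mean and SD over 4 arrays). Chromosomes II and III had medians of -0.25 and -0.30 on array 2 and 0.17 and 0.18 on array 3, and means of -0.01 and -0.03. An exact sign-flip test over 4 arrays cannot go below a p of 1 in 8, and none was used for the chromosomes.

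Dye orientation moved some genes strongly. The fit with a dye term called 4 genes at an adjusted p under 0.05 (734 at an unadjusted p under 0.05). These genes, named after their values were seen, were PIR1, CDA1, RSC2 and RPL10, and none of them passed for bre1 against wild type. PIR1 had log2 ratios of 1.72 and 1.19 on arrays 1 and 3 and of -2.12 and -2.28 on arrays 2 and 4. RPL10 ran the other way, with -0.48 and -0.88 on arrays 1 and 3 and 1.59 and 1.96 on arrays 2 and 4.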

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

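The tests of single dye orientations or arrays against length, and of the ribosomal protein excess per array, were chosen only after the result was seen. The other tests in this part were written down before their results were seen. Permutations over genes treat genes as independent, which they are not.

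Of 143 sets of 4 arrays examined (96 genes, 31 lists and 16 chromosomes), 3 held an array that stood apart from the others beyond Dixon's 95% critical value of 0.829, and chance alone gives about 1 in 20. OGG1 had a log2 ratio of 2.69 on array 3 and of 1.40, 1.58 and 1.37 on arrays 1, 2 and 4 (gap over range 0.842). RPT2 had 0.18 on array 3 and 1.05, 1.20 and 1.11 on the others (0.849). The median of chromosome VI, relative to that of all genes, was -0.02 on array 3 and -0.08, -0.09 and -0.09 on the others (0.836).

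The 410 genes of the main comparison were set against the other sign patterns of the 4 arrays. The real pattern alone gave as many (1 of 8), and the highest count among the other 7 was 0; with 8 patterns the share cannot go below 1 in 8, so this design is too small for a share under 0.05.

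Short genes were higher in bre1, and so were ribosomal protein genes, which are short. Without ribosomal protein and ribosome biogenesis genes the Spearman correlation of the mean log2 ratio with annotated gene length was still -0.231 over 3657 genes (permutation p = 0.0001, the smallest that 10000 shuffles can give), which argues against those genes as the whole source of the trend. The correlation was -0.243, -0.260, -0.081 and -0.192 on arrays 1 to 4, so that even its weakest value, -0.081, lay on the same side, which argues against 1 array or 1 dye orientation as the source. Ribosomal protein genes had a median of 0.66, against 0.13 for random lists matched on length (permutation p = 0.0001, the smallest possible). Those lists were drawn from genes that included the ribosomal protein genes. Ribosomal protein genes also lay 0.508 above the 20 other genes nearest in length (SD over genes 0.392). Both values argue against the length trend as the whole source of their rise in the mean. The excess over genes nearest in length was 0.39, 0.66 and 0.82 on arrays 1, 2 and 4. It was 0.06 on array 3, where the list's own median was -0.01, so that the argument rests on arrays 1, 2 and 4. Annotated lengths include introns, so some of these genes were matched to genes with longer transcripts; their median of 0.66 also lay above the 0.33 of other genes of at most 500 bp. A difference in RNA quality or labelling between the bre1 and wild-type RNA that runs the same way in each preparation, which may favour short transcripts, and an effect of bre1 on them both stay open, since each array sets the same 2 strains against each other.

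Genes at chromosome ends were lower in bre1. Places 6 to 10 from each end, without the families removed by name, still had a lower median than genes beyond place 10 (difference -0.157, 90 against 3625 genes, permutation p = 0.0011, 4 higher and 9 lower). This argues against probes that read several members of those families as the whole source. Families not removed by name could still share probe signal. The argument is weak, since the difference was smaller than in places 1 to 5 and camera gave this set an adjusted p of 0.0493 with the preset correlation and an adjusted p = 0.459 with an estimated correlation. Dim spots could not be examined directly; genes without a value on every array served in their place, and their medians differed from those of complete genes by -0.06, -0.06, 0.16 and -0.13 on arrays 1 to 4. The highest of these, 0.156, goes against a general loss of dim spots in bre1 while array 4 goes with it, so that this explanation cannot be told apart from an effect of position. An effect of bre1 that acts by position stays open and was not tested further.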

How the results depend on the processing

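The removal of a length trend, the dye term with an array left out, the positions by gene order, the ribosomal protein list without RPP1 and the estimated correlation without the repeated families were chosen only after the data were seen. No named gene or list that had passed changed direction under any alternative run. For named genes, 1013 of the comparisons with an alternative stayed on the same side of the threshold, 196 lost the call and 39 gained it; for the other lists than the subtelomeric one these numbers were 414, 26 and 11, and for that list 18, 3 and 0. The count of genes, 410 as deposited, was 467 after median centring (399 shared), 491 with scaling as well, 408 with values on at least 3 arrays, 402 with a robust variance prior, 440 with the length trend removed (321 shared) and 391 with a change of at least 1.5-fold. It was 897 with a dye term, 685 with array weights, 679 with arrays 1 and 2 and arrays 3 and 4 averaged as pairs, 1850 with arrays 1 and 4 and arrays 2 and 3 averaged, and 31 at an adjusted p under 0.01. Leaving out 1 array gave from 0 genes (limma, without array 2; 815 at an unadjusted p under 0.05) to 1066 (a dye term, without array 4), with 54, 187 and 677 without arrays 1, 3 and 4 and no dye term. With a dye term the 4 counts were 263, 564, 857 and 1066, so that without array 2 the dye term brought the count from 0 to 564. Of the variance of the 4 arrays over genes, 58.4% lay in their mean, 23.4% between dye orientations, 14.2% between arrays 1 and 2 and arrays 3 and 4, and 3.88% in what remained; the last share sets the spread when arrays 1 and 4 and arrays 2 and 3 are averaged. The share between arrays 1 and 2 and arrays 3 and 4 is a hint from the data, not from the labels, that these may be pairs, and the cause was not tested. Between 14 and 18 lists passed across the fits, 15 as deposited. Lists that passed in an alternative alone were cell wall integrity genes (values on at least 3 arrays, a dye term, either pairing, without array 4), Gcn4-regulated genes (values on at least 3 arrays, without array 1), auxotrophic markers (values on at least 3 arrays), hexose transporters (arrays 1 and 2 and arrays 3 and 4 as pairs), flocculins (without array 3) and G2/M genes (fry's directional test, adjusted p = 0.0284). With an estimated correlation, a run that also lowers the degrees of freedom of the test to 3, 0 passed. In fry's tests, which do not compare a list with other genes, 8 passed the directional test and 25 the mixed test. In the directional test 8 of the 15 lists lost their call: the subtelomeric, phosphate, iron, ribosomal protein, proteasome, glycolysis, daughter cell separation and COS lists, with adjusted p between 0.0535 and 0.234. The subtelomeric list (median -0.23) also lost its call with an estimated correlation (adjusted p = 0.355). It did so too without the families removed by name (median -0.19, adjusted p = 0.386), where Y′ reading frames with systematic names stayed in. Over its camera tests with the preset correlation the median lay between -0.45 and -0.12 and the adjusted p lay between 1.42e-11 and 0.0493. The mean log2 ratio of BRE1 ranged from -3.17 to -1.65 when an array was left out. A dye term, pair averages, array weights and the robust prior could not be applied to BRE1, which has values on 1 dye orientation, and a test of each probe was void because each gene has 1. Signal over background is not known here, so that its effect on weak spots stays open.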

Other observations

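The 5 gene families of this part were put together, and the test of membrane and secretory genes chosen, only after the calls were seen; the tests of neighbouring genes were written down before their results.

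The 4 families of membrane and secretory genes had medians below 0 and the mitochondrial ribosomal proteins a median above 0. Of 17 measured amino acid permease genes, 6 fell and none rose, with a median log2 ratio of -0.43 (camera adjusted p = 4.9e-05 over the 5 families); TAT1 had a log2 ratio of -0.97 ± 0.61 (SD, n = 4), DIP5 of -0.87 ± 0.53 and TAT2 of -0.87 ± 0.63. Of 9 drug and polyamine antiporter genes, 5 fell, TPO1 (-1.54), QDR2 (-0.95), QDR1 (-0.84), SGE1 (-0.83) and TPO4 (-0.58), with a median of -0.58 (adjusted p = 7.5e-04). Of 32 genes of protein glycosylation and GPI anchors, ALG6, PMT4 and PMT5 fell and ALG13 rose (1.04 ± 0.12), with a median of -0.34 (adjusted p = 5.3e-04). Of 31 genes of sterol and sphingolipid synthesis, 6 fell, among them SUR1 (-1.18 ± 0.21), LAC1 (-1.03 ± 0.67), ELO1 (-1.02 ± 0.80) and ERG5 (-0.98 ± 0.56), and LCB4 rose (0.65 ± 0.37), with a median of -0.34 (adjusted p = 1.4e-04). The glycosylation and lipid families had medians of 0.05 and 0.14 on array 4 and of -0.25 or lower on the others. Of 39 genes of mitochondrial ribosomal proteins, 4 rose and none fell, MRPL36 (0.88), MRPL32 (0.83), MRPS17 (0.83) and MRPL16 (0.72), with a median of 0.32 (adjusted p = 2.5e-05). Against other genes of like length their excess was 0.16 (SD over genes 0.30, above 0 for 31 of 39), with 0.32, 0.37, 0.15 and -0.04 on arrays 1 to 4. With an estimated correlation each of the 5 families had an adjusted p of 0.383.

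A hypothesis from these values is that transcripts of proteins made at the endoplasmic reticulum were lower in bre1 as a class. The 4 membrane and secretory families together (89 genes, 20 lower, 2 higher, 72 with a mean below 0) had a lower median than other genes of like length (difference -0.340, permutation p = 0.0001, the smallest that 10000 shuffles can give). Because the families were named from genes that had fallen, this difference does not decide the hypothesis, which may not hold in genes chosen otherwise. The families also take in soluble enzymes, such as those of ERG8, ERG12 and ERG20, so that they only approximate the class.

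Neighbouring genes had similar ratios. The Spearman correlation of mean log2 ratios between neighbours was 0.10 over 3795 pairs, above the highest of 10000 shuffled orders, 0.065 (permutation p = 0.0001, the smallest possible), and 0.075 without the outermost 15 genes per end, which is consistent with an effect of chromosome position. Position of the spots on the array, if probes were printed in the order of systematic names, could give the same. Contrasts between arrays hold no bre1 effect only if its size was the same on each array. Ratios spread more on array 1 (SD 0.67) than on arrays 3 and 4 (0.49), so these contrasts may hold some of it. In them neighbours correlated at 0.127 for dye orientation, above the highest of 1000 shuffles (0.055). For the other contrasts the correlations were 0.042 and 0.040, within their shuffles (0.054 and 0.057). The lowest, 0.040, neither reached the level that a print effect needs nor was near 0, so that these explanations cannot be told apart here.

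Of 2 marker genes with high ratios, HIS3 was at 1.49, 1.57, 1.06 and 1.05 on arrays 1 to 4. LYS2 was at 2.18, 2.82 and 1.29 on arrays 1, 3 and 4, the arrays that measured it, with a mean of 2.09 ± 0.77 (SD, n = 3), outside the test. The genotypes of the strains at these loci were not used here.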
